A study of Homo sapiens with 21 samples.

How the data were processed

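Poly(A) RNA of HL-60 cells was sequenced from stranded libraries, per the labels, in 21 libraries that form 7 groups of 3. The deposited table holds a read count per gene symbol and library, and the values are whole numbers whose sums differ between libraries. Per the submitters' processing notes, the authors made base calls with bcl2fastq 1.8.4, aligned reads with HISAT2 and counted them with HTSeq against the human builds hg19 and GRCh37. The versions of HISAT2 and HTSeq, the counting mode, the strand setting and the gene annotation are not given in the sources used here. Reads of genes with near-identical copies may therefore have been left out or assigned to other copies, and coordinates are not given because the table names genes by symbol only.

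The table had 23368 genes, of which 5853 had no count in any library. All 21 columns were matched to a sample by their title. A second tag in the labels, which also names a perturbation, gave the same group as the title for only 3 of the 21 libraries and formed 8 groups. A test for any difference between groups called 2520 genes with groups taken from the titles and 0 with groups taken from the tag (edgeR, adjusted p under 0.05), and the titles were used.

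Total counts per library ran from 12082028 to 19394758. The analysis used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The filter filterByExpr, with a minimum count of 10 and a minimum total of 15, kept 11833 genes. Libraries were scaled by TMM factors, which lay between 0.973 and 1.011. Negative binomial models with a term for each group were fitted to all 21 libraries by edgeR's robust quasi-likelihood method, which left 14 residual degrees of freedom. The biological coefficient of variation was 9.59%. Each contrast was tested with the quasi-likelihood F test, two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested in that contrast, with a threshold of 0.05. Standard errors (SE) of log2 differences came from the same fit, and expression is given as CPM from edgeR's cpm function, which scales counts by the TMM-adjusted library total, as mean ± SD with n = 3 libraries per group. Where every library of a group was at 0, a fold was computed against a floor of 3 counts over the group and is a lower bound. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules.

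The 14 contrasts were 11 differences between 2 groups and 3 interactions. The groups, contrasts, 28 gene lists, the rule for named genes and the alternative settings listed below were fixed before the data were examined. By that rule each comparison of groups named up to 8 genes higher and 8 lower. These had the largest change among genes past the threshold with a mean of at least 1 CPM and no overlap between the libraries of the groups. The rule added up to 4 called members of each list with the largest change. Each interaction could name up to 5 genes per direction. KAT2A, KAT2B, KDM1A, CYP26A1, ITGAM, CD38 and CD86 were always named, and where no gene was called the 3 with the smallest p were named as not passing. The text gives a selection of the genes so named. Genes outside the rule are marked as chosen after their values were seen.

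Gene lists were tested with camera from limma on voom values with a preset correlation of 0.01, adjusted over the 23 lists with enough tested members. Camera was also run with a correlation estimated for each list. Other alternatives were RLE size factors, no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, a fit to only the groups of the contrast, and leaving out each library in turn. The DESeq2 Wald test, a rotation test of the lists (fry) and a block for the replicate number were further alternatives. The interactions compared the effect of a compound in 2 backgrounds.

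The titles number the replicates 1 to 3 in every group. To check whether these numbers pair libraries, the deviations of each library from its group mean were correlated across genes, which are not independent replicates. Of the 63 pairs of libraries from different groups with the same number, 62 had a correlation over 0.1, with a median of 0.30. The 126 pairs with different numbers had a median of -0.17. The numbers paired libraries in 13 of the 14 contrasts. A block for the number was fitted as an alternative, with 12 residual degrees of freedom, and its counts stand beside the results. Unless the block is named, the p-values, SE and estimated correlations come from fits without it. Those fits leave the spread shared by a replicate number in the residuals. The labels do not say what the numbers share, nor whether replicates are separate cultures, so p-values measure the spread between these samples. Without the block, 0.659% to 3.45% of tested genes had an unadjusted p under 0.05, in comparisons that isolate inhibitors and in interactions. A calibrated test without any effect gives a share of 0.05, so these tests were conservative. Such counts are thus no sign of an effect, and a lack of calls does not exclude one.

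Choices made after seeing the data were the effect of MB3 and that of GSK-LSD1 averaged over 3 backgrounds, a fit without the pair of libraries that stood apart, and the replicate block with a correction of each library for GC content and gene length. GC content and length were those of the longest GENCODE v29 transcript of each gene symbol, with older symbols matched through RefSeq synonyms, and were available for 96.3% of the tested genes.

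The model was tested on counts simulated from the means, dispersions and depths of these libraries, with 200 genes of at least 1 CPM changed by 1.5, 2 or 4-fold in either direction. In the setting of MB3 against untreated cells, 70.15% of 1.5-fold changes, 92.5% of 2-fold changes and 98.5% of 4-fold changes were recovered. In the setting of ATRA with GSK-LSD1 against ATRA, the shares were 70.15%, 94.0% and 98.5%. Besides these, 11 and 8 genes simulated without a change were called. Each simulated gene took the dispersion of the fitted trend at its mean. The simulation held no effect of the replicate number and no libraries that stood apart. It also changed 200 genes at once, which makes the adjusted threshold easier to pass than in comparisons with few calls. Its recovery can therefore be higher than that in the real data.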

Results

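HL-60 cells, a human acute myeloid leukaemia line that can mature along the granulocyte path, were treated for 3 h and their poly(A) RNA was sequenced. The compounds were all-trans retinoic acid (ATRA, 100 nM), which activates retinoic acid receptors, MB3 (50 µM), an inhibitor of the histone acetyltransferase GCN5 (KAT2A), and GSK-LSD1 (1 nM), an inhibitor of the histone demethylase LSD1 (KDM1A). The 7 groups were untreated cells, each compound alone, ATRA with MB3, ATRA with GSK-LSD1, and ATRA with both inhibitors, with 3 libraries in each. No group had MB3 and GSK-LSD1 without ATRA, and no vehicle is named in the labels for the untreated cells. Total counts per library lay between 12082028 and 19394758, and 14065 to 14832 genes had at least 1 count. The 10 most abundant genes held 3.73% to 4.39% of the counts.

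The first principal component held 55.0% of the variance and parted the 12 libraries with ATRA, at -26.9 to -13.7, from the 9 without, at 24.7 to 31.8. The second component held 10.4%. ATRA+MB3 replicate 1 and ATRA+GSK-LSD1+MB3 replicate 1 stood apart from the other libraries, with an SD of their deviations from the group mean of 0.236 and 0.282 on the log2 scale against at most 0.219 elsewhere.

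**Figure D1:**
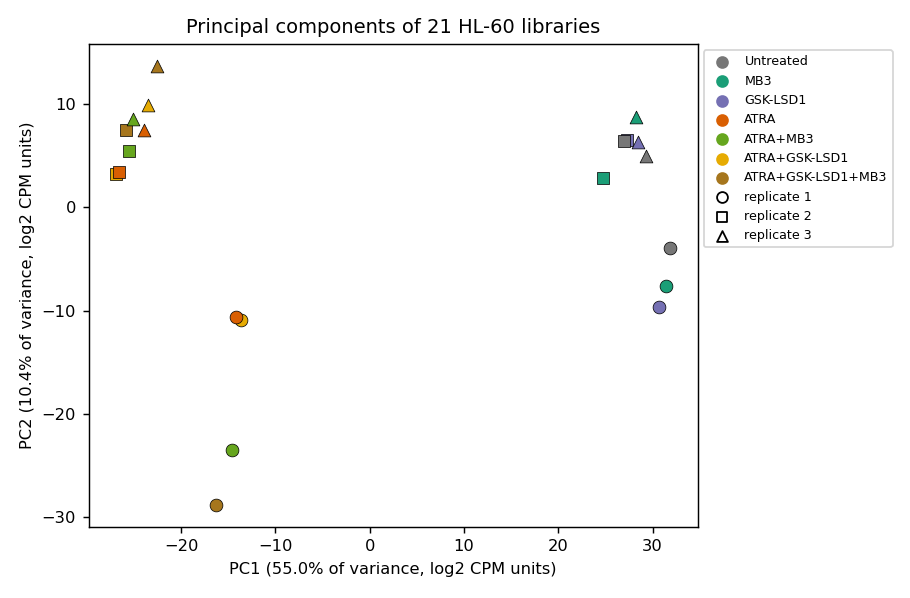
Principal components 1 and 2 of log2 CPM for the 21 libraries, in log2 CPM units, with colours for groups and marker shapes for replicate numbers. The 12 libraries with ATRA lie at -26.9 to -13.7 on the first component and the 9 without it at 24.7 to 31.8.

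The comparison of ATRA with untreated cells asks which genes 3 h of ATRA changed. Most tested genes of the retinoid response list rose. DHRS3, a retinaldehyde reductase, went from 1.96 ± 0.461 to 159 ± 26.6 CPM (n = 3), a log2 difference of 6.32 (SE 0.179, adjusted p = 8.07e-16). HIC1, a transcriptional repressor that responds to retinoic acid, went from 0.549 ± 0.0604 to 93.1 ± 14.7 CPM, a log2 difference of 7.38 (SE 0.223). TGM2, a transglutaminase, had no count in the untreated libraries and 1.84 ± 1.07 CPM with ATRA, at least 25.6-fold higher, a call lost without a filter on low counts (adjusted p = 0.0586, range over all alternatives 1.36e-07 to 0.0586). PTGES, a prostaglandin E synthase, was at least 113-fold higher on the same floor of 3 counts over the group. CYP26A1, the retinoic acid hydroxylase, had 0 counts in the untreated group and 7 with ATRA, too few to be tested. In the fixed list of retinoid response genes, 13 of 19 tested members rose, 2 fell and 4 did not pass, with 14 and 2 adjusted over the list alone. The median log2 difference of the list was 1.37, also with TGM2 at its bound. The 2 that fell were RXRA, a retinoid X receptor, by 0.63 (SE 0.0953), and RDH10, a retinol dehydrogenase, by 0.44 (SE 0.11), both named after their values were seen. The list was higher by camera (adjusted p = 8.46e-12; adjusted p = 0.0389 with an estimated correlation).

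Genes of granulocyte maturation also rose. FGR, a myeloid tyrosine kinase, went from 1.41 ± 0.328 to 156 ± 48.2 CPM (log2 difference 6.80, SE 0.412). ITGAX, the CD11c integrin chain, rose by 4.27 on the log2 scale (SE 0.487). NCF1, a subunit of the phagocyte NADPH oxidase that has pseudogene copies, rose by 3.72 (SE 0.321). CEBPE, a transcription factor of late granulocyte maturation, went from 62.8 ± 4.51 to 191 ± 12.1 CPM (log2 difference 1.61, SE 0.0831). CD38, an ectoenzyme that retinoids raise, went from 10.9 ± 2.50 to 73.2 ± 13.0 CPM (log2 difference 2.75, SE 0.236, adjusted p = 3.62e-08). ITGAM, the CD11b integrin chain, went from 2.80 ± 0.478 to 7.64 ± 4.03 CPM (log2 difference 1.45, SE 0.388, adjusted p = 0.0127). That call was lost without Untreated replicate 2 or without ATRA replicate 3, with adjusted p from 0.000124 to 0.142 over the alternatives. CD86, a costimulatory receptor, was at 3.32 ± 1.27 and 4.88 ± 1.37 CPM and did not pass (log2 difference 0.56, SE 0.437, adjusted p = 0.46), but passed with the replicate block (adjusted p = 0.00845). Of the 18 tested members of the granulocyte list, 10 rose, none fell and 8 did not pass, with 11 higher adjusted over the list alone. The list was higher by camera (adjusted p = 1.43e-08), with adjusted p = 0.132 with an estimated correlation.

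**Figure D2:**
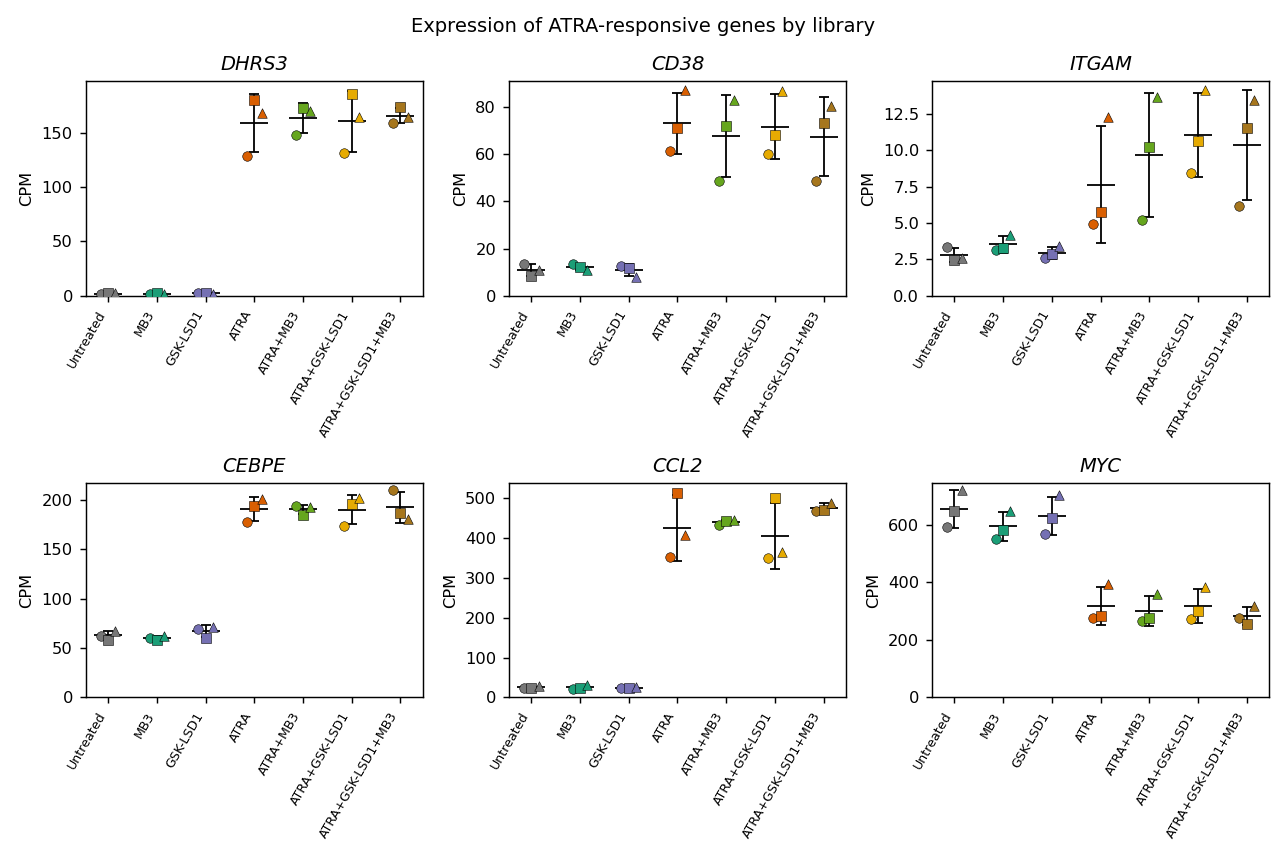
CPM of 6 genes in each library by group, with circles, squares and triangles for replicates 1, 2 and 3 and bars for the group mean and SD (n = 3). DHRS3 lies near 1.96 CPM in untreated cells and 159 CPM with ATRA, and MYC near 655 and 318 CPM.

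MYC and 15 of 33 tested genes of MYC targets and ribosome production fell with ATRA. MYC went from 655 ± 65.6 to 318 ± 65.5 CPM, and fell by 1.04 on the log2 scale (SE 0.148, adjusted p = 2.85e-05). None of the list rose and 18 did not pass, with 24 lower adjusted over the list alone. Among those that fell, POLR1B, a subunit of RNA polymerase I, fell by 0.64 (SE 0.114) and PPAT, an enzyme of purine synthesis, by 0.65 (SE 0.0801). The list was lower by camera (adjusted p = 2.32e-10), with adjusted p = 0.379 with an estimated correlation. In the list of HOX and stem cell genes, 2 of 14 rose and 4 fell, with 3 and 6 adjusted over the list alone. HOXA4 rose by 2.13 (SE 0.362), and GATA2, a stem cell transcription factor, fell by 1.49 (SE 0.252).

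Genes of growth arrest, cell death and inflammation changed as well. CDKN1A, the cell cycle inhibitor p21, rose by 2.25 on the log2 scale (SE 0.308) and CDKN2D by 1.76 (SE 0.245), while BIK, a promoter of apoptosis, rose by 2.86 (SE 0.153) and BCL2A1, an inhibitor of apoptosis, by 1.76 (SE 0.164). Of 23 tested members of the cell death and growth arrest list, 8 rose and 3 fell, with 8 and 4 adjusted over the list alone. Camera gave adjusted p = 0.00448, with adjusted p = 0.115 with an estimated correlation. In the NF-kB list, 10 of 23 rose and 2 fell, with 11 and 4 adjusted over the list alone (camera adjusted p = 0.00167; adjusted p = 0.314 with an estimated correlation). CCL2, a monocyte chemokine, went from 25.2 ± 2.40 to 424 ± 82.2 CPM (log2 difference 4.07, SE 0.152), IL8, a neutrophil chemokine, rose by 2.03 (SE 0.136) and ICAM1, an adhesion receptor, by 3.77 (SE 0.411). In the interferon list, 4 of 22 rose and 2 fell, with 7 and 2 adjusted over the list alone (camera adjusted p = 0.019; adjusted p = 0.379 with an estimated correlation). IRF1 rose by 1.92 (SE 0.149) and IFI6 by 3.20 (SE 0.685).

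The other lists were not called by camera for ATRA. In the monocyte and macrophage list, 2 of 19 rose and 6 fell, with 3 and 7 adjusted over the list alone. CCR2, a chemokine receptor, rose by 1.62 (SE 0.178), and KLF4, a monocyte transcription factor, fell by 1.64 (SE 0.308). In the immediate early list, 7 of 23 rose and 6 fell, with 10 and 6 adjusted over the list alone, and JUN fell by 2.27 (SE 0.226). In the list of LSD1 inhibitor response genes, 4 of 14 rose and 3 fell, with 5 and 3 adjusted over the list alone. Among these GFI1, a repressor that binds LSD1, rose by 0.65 (SE 0.0582) and GPR65, a proton-sensing receptor, fell by 1.01 (SE 0.135). Of the promyelocyte granule genes, 2 of 12 rose and 3 fell, with 2 and 4 adjusted over the list alone. Of the glycolysis and hypoxia genes, 1 of 22 rose and 4 fell, the same counts as adjusted over the list alone. NDRG1 rose by 2.61 (SE 0.201), and HK2, a hexokinase, fell by 1.05 (SE 0.142). In the integrated stress list, 3 of 26 rose and 2 fell, the same counts as adjusted over the list alone, and DDIT4, an inhibitor of mTOR signalling, rose by 2.63 (SE 0.224). Of the cholesterol genes, 2 of 21 rose and 0 fell, also adjusted over the list alone, and ABCA1, a cholesterol exporter, rose by 1.68 (SE 0.375).

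In the remaining lists few members passed without the block. Of the unfolded protein response genes 2 of 19 rose, and of the NRF2 genes 1 of 23 rose, the same counts as adjusted over the list alone. In the G1/S list 2 of 26 rose, 1 adjusted over the list alone, and in the G2/M list 1 of 26 rose under either adjustment. Of the heat shock genes 1 of 18 fell and 0 adjusted over the list alone, and of the 6 metallothioneins 0 passed by edgeR under either adjustment. Among subunits of the GCN5 complexes SAGA and ATAC, 2 of 27 fell, 1 adjusted over the list alone. Among subunits of the LSD1 complex 1 of 14 rose and 2 fell, the same counts as adjusted over the list alone. KDM1A itself fell by 0.27 (SE 0.0565, adjusted p = 0.00173). KAT2A and KAT2B were not called, with log2 differences of 0.03 (SE 0.0986) and 0.06 (SE 0.151). Of the markers of other cell types, 2 erythroid, 1 lymphoid, 2 megakaryocyte, 3 eosinophil or mast cell and 1 fibroblast gene were tested. The lymphoid gene passed, higher, only when adjusted over its list alone. The erythroid EPOR rose by 0.77 (SE 0.167), VIM fell by 0.49 (SE 0.104) and the mast cell gene MS4A2 fell by 0.64 (SE 0.196, adjusted p = 0.0303). The MS4A2 call was lost without Untreated replicate 1, ATRA replicate 2, ATRA replicate 3 or Untreated replicate 3, and over all its alternatives the adjusted p ran from 0.0133 to 0.114. No mitochondrially encoded gene of the fixed list was in the table.

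In all, edgeR called 1844 of 11833 genes for ATRA, 977 higher and 867 lower, and 439 of them changed at least 2-fold. Without ATRA replicate 2 the counts were 733 higher and 522 lower, and without ATRA replicate 3 they were 772 higher and 556 lower. SERPINB2, a plasminogen activator inhibitor, had the largest fall among the named genes, by 3.11 (SE 0.297), and FAM46C fell by 2.62 (SE 0.149). RPS18, a ribosomal protein gene with near-identical copies, was at 17.1 ± 3.93 and 2.48 ± 3.50 CPM (adjusted p = 0.0357), a call lost with the replicate block (adjusted p = 0.0627) and when any library but ATRA replicate 2 was left out (range over all alternatives 0.00547 to 0.151). The replicate block called 3141 genes, 1574 higher and 1567 lower, and DESeq2 called 1927. With the block and the GC and length correction, 4286 were called and the split moved to 1750 higher and 2536 lower. That correction also removes each library's mean deviation across genes, changes due to ATRA included. The median log2 difference moved from 0.0035 with the block to -0.028 with the correction. The shift of the split towards lower genes can therefore not be read as an effect of ATRA.

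The next question was what MB3 changed, in untreated cells and on top of ATRA. In untreated cells, genes that respond to oxidative stress rose with MB3. OSGIN1, a regulator induced by oxidative stress, went from 1.02 ± 0.167 to 4.86 ± 0.661 CPM (n = 3, log2 difference 2.24, SE 0.26, adjusted p = 0.000343). MAFG, a small MAF protein that pairs with NRF2, went from 160 ± 13.7 to 241 ± 18.1 CPM (log2 difference 0.59, SE 0.0749, adjusted p = 0.000783). TXNRD1, thioredoxin reductase, went from 315 ± 16.3 to 422 ± 16.3 CPM (log2 difference 0.42, SE 0.0697, adjusted p = 0.0224), and LRP12, a receptor of the LDL receptor family, from 26.9 ± 1.01 to 39.6 ± 3.27 CPM (log2 difference 0.56, SE 0.101, adjusted p = 0.0454). Of the 23 tested NRF2 genes, 2 rose and 21 did not pass without the replicate block, with 9 higher adjusted over the list alone, and 8 rose with the block. Among those 9, and named after their values were seen, NQO1, a quinone reductase, had a log2 difference of 0.58 (SE 0.13), GCLM, a subunit of the enzyme of glutathione synthesis, 0.68 (SE 0.15), and SRXN1, sulfiredoxin, 0.50 (SE 0.112). These 3 also passed over all genes with the block (adjusted p = 0.00187, 0.00784 and 2.68e-05). The NRF2 list was higher by camera (adjusted p = 5.36e-22; adjusted p = 0.000299 with an estimated correlation).

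In all, edgeR called 5 genes for MB3 in untreated cells, 4 higher and 1 lower, with 226 genes at an unadjusted p under 0.05 and 4 calls by DESeq2. The gene that fell, GTF2H2B, is named after its values were seen. It was at 1.24 ± 0.379 CPM in untreated cells and at 0.119 to 0.286 CPM, as group means, in the other 6 groups. The replicate block called 23 genes, 20 higher and 3 lower, and with the GC and length correction 47, 38 higher and 9 lower. Without any 1 of the 6 libraries the count was 2, and the calls of TXNRD1, LRP12 and GTF2H2B were lost each time, with adjusted p from 4.67e-07 to 0.325 for TXNRD1 and from 6.83e-06 to 0.466 for LRP12 over their alternatives. The LRP12 call was also lost with RLE size factors and with the filter of 1 CPM. Camera also called 9 further lists with the preset correlation, of which heat shock (adjusted p = 0.000559), integrated stress (adjusted p = 0.000951), cell death (adjusted p = 0.00409) and unfolded protein response (adjusted p = 0.00473) were higher and cholesterol synthesis (adjusted p = 0.00206) was lower. No member of these 5 lists was called by edgeR without the block, also adjusted over the list alone, and their adjusted p was 0.602, 0.681, 0.108, 0.681 and 0.709 with an estimated correlation. With the block 2 heat shock genes were called higher and 1 cholesterol gene lower. Camera with the block and an estimated correlation together called 3 of the 23 lists, against 1 with an estimated correlation alone. Granulocyte maturation and immediate early genes were higher and MYC targets lower, each with adjusted p = 0.0441, and G1/S genes were lower with adjusted p = 0.0483. No member of these was called by edgeR under either adjustment, and their adjusted p was 0.693, 0.681, 0.795 and 0.693 with an estimated correlation.

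**Figure D3:**
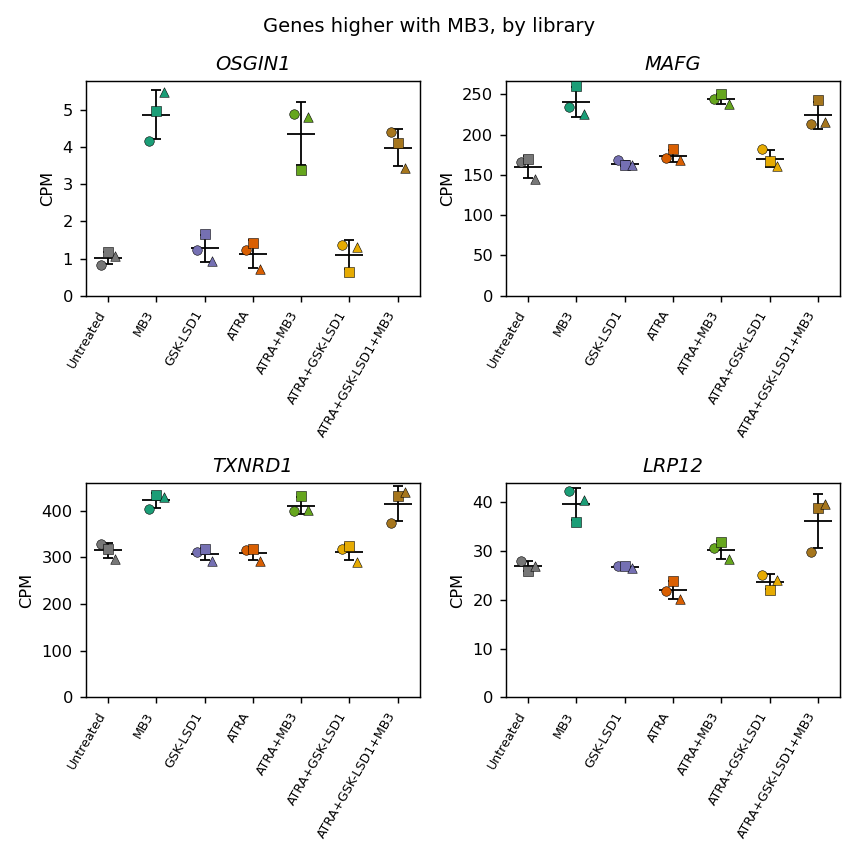
CPM of OSGIN1, MAFG, TXNRD1 and LRP12 in each library by group, with circles, squares and triangles for replicates 1, 2 and 3 and bars for the group mean and SD (n = 3). OSGIN1 lies at 1.02 CPM in untreated cells, 4.86 with MB3, 1.12 with ATRA and 4.36 with ATRA and MB3.

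On top of ATRA, members of the same NRF2 list rose with MB3, as did MAFG, which is not on the list. In ATRA with MB3 against ATRA, OSGIN1 went from 1.12 ± 0.367 to 4.36 ± 0.838 CPM (log2 difference 1.96, SE 0.265, adjusted p = 0.0038), MAFG rose by 0.49 (SE 0.0749, adjusted p = 0.0109) and TXNRD1 by 0.41 (SE 0.0697, adjusted p = 0.0318). These were the 3 genes called by edgeR, all higher, with 323 at an unadjusted p under 0.05, 5 calls by DESeq2, 13 with the replicate block (12 higher and 1 lower), 55 with the block and the GC and length correction (42 higher and 13 lower) and 0 in a fit to these 6 libraries alone. Of the 23 NRF2 genes 2 were called higher, 6 with the block and 9 adjusted over the list alone (camera adjusted p = 1.22e-22; adjusted p = 0.000255 with an estimated correlation). Camera called 7 further lists with the preset correlation. Heat shock (adjusted p = 8.84e-07), integrated stress (adjusted p = 5.80e-06), immediate early (adjusted p = 2.07e-05) and unfolded protein response genes (adjusted p = 0.000133) were higher and cholesterol genes lower (adjusted p = 0.00808). Their adjusted p was 0.288, 0.406, 0.288, 0.406 and 0.856 with an estimated correlation. G2/M genes (adjusted p = 0.0217; adjusted p = 0.856 with an estimated correlation) and glycolysis genes (adjusted p = 0.0372; adjusted p = 0.406 with an estimated correlation) were higher. No member of these 7 lists was called by edgeR without the block, and 1 immediate early gene passed adjusted over the list alone. With the block 1 heat shock gene was called higher. Camera with the block and an estimated correlation together called 5 of 23 lists, against 1 with an estimated correlation alone. The count was 1 without ATRA+MB3 replicate 1, ATRA replicate 1 or ATRA+MB3 replicate 2, and 0 without ATRA replicate 3. The OSGIN1 call was lost without ATRA replicate 3, that of MAFG without any of those 4 libraries, and that of TXNRD1 without any 1 of the 6, with adjusted p over the alternatives from 5.46e-06 to 0.218, 4.72e-07 to 0.274 and 1.64e-06 to 0.68.

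The differentiation markers ITGAM, CD38 and CD86 were not called for MB3 on top of ATRA. ITGAM was at 7.64 ± 4.03 CPM with ATRA and 9.69 ± 4.26 CPM with ATRA and MB3 (log2 difference 0.37, SE 0.333), CD38 had a log2 difference of -0.10 (SE 0.206) and CD86 of 0.41 (SE 0.40). The lists of retinoid response and granulocyte maturation had 0 calls by edgeR there without the block and were not called by camera. With the replicate block TNFAIP2, a member of the retinoid list named after its values were seen, rose by 0.61 (SE 0.0842, adjusted p = 0.00101). It was also called with the block for MB3 in untreated cells and on top of ATRA with GSK-LSD1, by 0.50 and 0.59.

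In ATRA with both inhibitors against ATRA with GSK-LSD1, which also isolates MB3, OSGIN1 went from 1.10 ± 0.394 to 3.98 ± 0.491 CPM (log2 difference 1.82, SE 0.267, adjusted p = 0.0126). LRP12 rose by 0.60 (SE 0.102, adjusted p = 0.0327) and TXNRD1 by 0.41 (SE 0.0697, adjusted p = 0.0327). EdgeR called only these 3, with 408 at an unadjusted p under 0.05, 7 calls by DESeq2, 25 with the replicate block (22 higher and 3 lower), 71 with the block and the GC and length correction (55 higher and 16 lower) and 0 in a fit to these 6 libraries alone. Of the 23 NRF2 genes 2 rose, 7 with the block and 12 adjusted over the list alone (camera adjusted p = 2.08e-22; adjusted p = 0.000268 with an estimated correlation). Cholesterol genes were again lower with the preset correlation (adjusted p = 0.00161; adjusted p = 0.729 with an estimated correlation). The HOX and stem cell list was lower as well (adjusted p = 0.0124; adjusted p = 0.154 with an estimated correlation), with 0 of 14 called and 1 lower adjusted over the list alone. The other 7 lists called, all higher, were heat shock, unfolded protein response, integrated stress, NF-kB, G2/M, immediate early and cell death, with adjusted p from 2.76e-08 for heat shock to 0.00952 for cell death. With an estimated correlation these had an adjusted p from 0.154 to 0.51. None of their members was called by edgeR without the block, and 1 cell death gene passed adjusted over the list alone. With the replicate block 1 heat shock, 1 cell death and 1 NF-kB gene were called higher, and 2 cholesterol genes and 1 HOX or stem cell gene lower. Camera with the block and an estimated correlation together called 7 of 23 lists, against 1 with an estimated correlation alone. The count was 6 without ATRA+GSK-LSD1+MB3 replicate 1, 1 without ATRA+GSK-LSD1 replicate 1 or ATRA+GSK-LSD1+MB3 replicate 3, and 0 without ATRA+GSK-LSD1+MB3 replicate 2, ATRA+GSK-LSD1 replicate 2 or ATRA+GSK-LSD1 replicate 3. The OSGIN1 call was lost without any of the last 3, and those of LRP12 and TXNRD1 without any but ATRA+GSK-LSD1+MB3 replicate 1. Over the alternatives the adjusted p ran from 0.000132 to 0.753 for OSGIN1, from 1.75e-05 to 1 for LRP12 and from 4.88e-07 to 1 for TXNRD1. Without both libraries that stood apart it was 10.

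Across the 3 comparisons that isolate MB3, which share no library, OSGIN1 and TXNRD1 were the 2 genes called each time by edgeR. With the replicate block 11 genes were called in all 3, among them NQO1, SRXN1, SQSTM1, PGD and DNAJB1, named after their values were seen. The 34 genes called with the block in at least 1 of the 3 had the same sign in all 3 for 33. On the NRF2 list, 8 members passed in each comparison when adjusted over the list alone. They were NQO1, GCLM, TXNRD1, SRXN1, OSGIN1, SQSTM1, PGD and GSR.

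GSK-LSD1 was compared in the same way, to see what LSD1 inhibition changed. In untreated cells edgeR called 1 gene, GTF2H2B, which is described above and fell by 2.97 (SE 0.471, adjusted p = 0.038). The block called 1 gene, DESeq2 called 0, and 101 genes had an unadjusted p under 0.05. The count was 0 without any 1 of the 6 libraries. The list of LSD1 inhibitor response genes had 0 of 14 called, also adjusted over the list alone, with positive differences for 11 (camera adjusted p = 0.00765; adjusted p = 0.907 with an estimated correlation). With the block, 2 members passed adjusted over the list alone. Camera with the block and an estimated correlation together called 1 of 23 lists, against 0 with an estimated correlation alone.

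On top of ATRA, 0 genes were called by edgeR for GSK-LSD1, also with the replicate block, but 3, all higher, with the block and the GC and length correction. DESeq2 called 0, and 98 genes had an unadjusted p under 0.05. The 3 genes with the smallest p, none past the threshold, were GPR65, GFI1 and PDGFA. GPR65 was at 5.40 ± 0.122 CPM with ATRA and 8.85 ± 0.951 with ATRA and GSK-LSD1 (log2 difference 0.71, SE 0.137, adjusted p = 0.482), and GFI1 at 361 ± 7.75 and 429 ± 25.3 CPM (log2 difference 0.25, SE 0.0577, adjusted p = 1). PDGFA, a growth factor, had a log2 difference of -0.54 (SE 0.145, adjusted p = 1). The 2 genes GPR65 and GFI1 passed when adjusted over the LSD1 inhibitor list alone (camera adjusted p = 0.00203 for the list; adjusted p = 0.654 with an estimated correlation). With the block, 3 members passed adjusted over the list alone. Camera with the block and an estimated correlation together called 2 of 23 lists, against 0 with an estimated correlation alone. ITGAM was at 7.64 ± 4.03 and 11.1 ± 2.86 CPM and did not pass (log2 difference 0.53, SE 0.335), and CD38 and CD86 had log2 differences of -0.03 (SE 0.206) and 0.29 (SE 0.409).

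**Figure D4:**
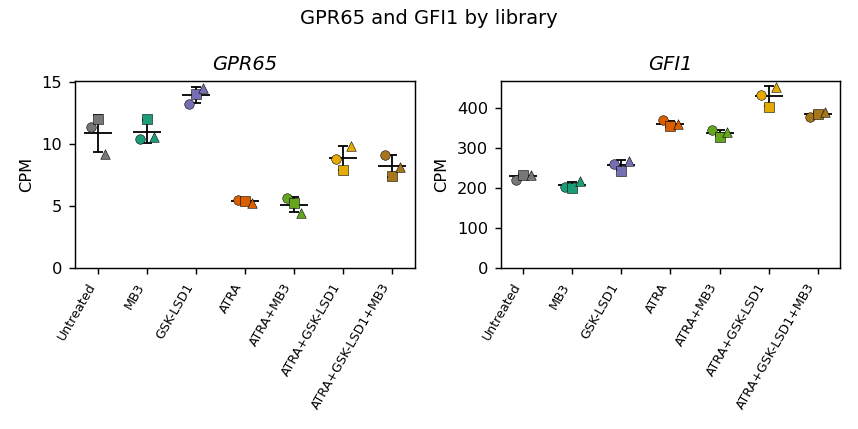
CPM of GPR65 and GFI1 in each library by group, with circles, squares and triangles for replicates 1, 2 and 3 and bars for the group mean and SD (n = 3). GPR65 lies at 5.40 CPM with ATRA and 8.85 CPM with ATRA and GSK-LSD1.

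In ATRA with both inhibitors against ATRA with MB3, edgeR also called 0 genes, with and without the block, DESeq2 called 1, and 189 had an unadjusted p under 0.05. The smallest p-values belonged to GPR65 (log2 difference 0.69, SE 0.136, adjusted p = 0.55), EVI2B, a membrane protein of blood cells (log2 difference 0.31, SE 0.0644, adjusted p = 0.55), and FONG (log2 difference 1.41, SE 0.348, adjusted p = 1). The LSD1 inhibitor list was higher (camera adjusted p = 0.0231; adjusted p = 0.937 with an estimated correlation), with 2 of 14 passing when adjusted over the list alone. The NF-kB list was higher too, with 0 of 23 called (camera adjusted p = 0.0231; adjusted p = 0.937 with an estimated correlation). Camera with an estimated correlation called 0 of 23 lists here, with and without the block. The libraries that stood apart lie in these groups.

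ATRA with both inhibitors against ATRA asks what the inhibitors added together. OSGIN1 rose by 1.82 (SE 0.271, adjusted p = 0.00749), LRP12 by 0.72 (SE 0.103, adjusted p = 0.00749) and TXNRD1 by 0.43 (SE 0.0698, adjusted p = 0.0198). These were the 3 calls by edgeR, with 353 genes at an unadjusted p under 0.05, 7 calls by DESeq2, 33 with the replicate block (31 higher and 2 lower), 73 with the block and the GC and length correction (55 higher and 18 lower) and 0 in a fit to these 6 libraries alone. Of the NRF2 genes 2 of 23 rose, 8 with the block and 10 adjusted over the list alone (camera adjusted p = 1.92e-23; adjusted p = 0.000213 with an estimated correlation). The monocyte and macrophage list was higher with the preset correlation (adjusted p = 0.0119; adjusted p = 0.533 with an estimated correlation), with 0 of 19 called. The same held for the LSD1 inhibitor list (adjusted p = 0.0039; adjusted p = 0.238 with an estimated correlation), with 0 of 14 called and 1 adjusted over the list alone. The 8 other lists called were heat shock, unfolded protein response, integrated stress, G2/M, NF-kB, immediate early and cell death, all higher, and cholesterol, which was lower. Their adjusted p ran from 1.86e-09 to 0.0439, and from 0.185 to 0.746 with an estimated correlation. None of their members was called by edgeR without the block, and 1 cell death gene passed adjusted over the list alone. With the replicate block 2 heat shock, 1 cell death and 1 NF-kB gene were called higher and 1 cholesterol gene lower. Camera with the block and an estimated correlation together called 9 of 23 lists, against 1 with an estimated correlation alone. ITGAM, CD38 and CD86 were not called, with log2 differences of 0.45 (SE 0.335), -0.12 (SE 0.206) and 0.50 (SE 0.402). The count was 5 without ATRA+GSK-LSD1+MB3 replicate 1, 1 without ATRA+GSK-LSD1+MB3 replicate 3, and 0 without ATRA replicate 1, ATRA+GSK-LSD1+MB3 replicate 2 or ATRA replicate 3. The OSGIN1 call was lost without any of the last 3, that of LRP12 also without ATRA+GSK-LSD1+MB3 replicate 3, and that of TXNRD1 without any but ATRA+GSK-LSD1+MB3 replicate 1. Over the alternatives the adjusted p ran from 7.65e-05 to 0.568 for OSGIN1 and from 1.72e-06 to 1 for both LRP12 and TXNRD1. Without both libraries that stood apart it was 8.

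ATRA with both inhibitors against untreated cells gave the changes of the full combination. DHRS3 rose by 6.38 (SE 0.179), CD38 by 2.63 (SE 0.236), ITGAM by 1.90 (SE 0.376, adjusted p = 0.000956) and CEBPE by 1.62 (SE 0.0831). MYC fell by 1.21 (SE 0.149). PTGES and TGM2 were at least 107-fold and 22.5-fold higher on the floor of 3 counts over the untreated group. Of the retinoid list 14 of 19 rose and 2 fell (camera adjusted p = 2.73e-11; adjusted p = 0.0387 with an estimated correlation), the same counts as adjusted over the list alone. Of 18 granulocyte genes 10 rose, and 11 rose and 1 fell adjusted over the list alone (camera adjusted p = 8.73e-09; adjusted p = 0.0949 with an estimated correlation). Of the NRF2 genes 10 of 23 rose, 15 rose and 1 fell with the block, and 12 rose and 1 fell adjusted over the list alone (camera adjusted p = 4.98e-05; adjusted p = 0.0861 with an estimated correlation). Of 33 MYC and ribosome genes 17 fell, and 21 adjusted over the list alone (camera adjusted p = 7.33e-10; adjusted p = 0.274 with an estimated correlation). Of 23 cell death genes 11 rose and 1 fell, and 11 and 3 adjusted over the list alone (camera adjusted p = 0.000381; adjusted p = 0.0387 with an estimated correlation). EdgeR called 2170 genes, 1126 higher and 1044 lower, and DESeq2 called 2283. The replicate block, although its numbers did not pair in this contrast, called 3546 genes, and the block with the GC and length correction 4622, 1963 higher and 2659 lower. The correction again recentred the libraries, and the median log2 difference moved from 0.006 to -0.022, so this split is not read as a result. A fit to these 6 libraries alone called 1251.

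Whether the inhibitors altered the response to ATRA was asked by comparing it with and without each. ATRA with MB3 against MB3 called 1837 genes by edgeR, 972 higher and 865 lower (3204 with the block, 1952 by DESeq2). Of the 1844 genes that ATRA changed in untreated cells, 1441 were also called here, 781 higher and 660 lower, where independent calls would share 80.3 and 63.4. CD38 rose by 2.49 (SE 0.23), and MYC fell by 0.98 (SE 0.148). With GSK-LSD1, ATRA called 1737 genes, 925 higher and 812 lower (2988 with the block, 1859 by DESeq2). Without ATRA+GSK-LSD1 replicate 2 the counts were 719 higher and 479 lower, and without ATRA+GSK-LSD1 replicate 3 they were 755 higher and 522 lower. Of the calls with all libraries, 785 higher and 644 lower were shared with ATRA alone, against 76.4 and 59.5 for independent calls. With the block and the GC and length correction the counts were 4357 with MB3, 1742 higher and 2615 lower, and 4256 with GSK-LSD1, 1674 higher and 2582 lower. Here too the correction recentred the libraries. The median log2 difference moved from 0.0055 to -0.025 with MB3 and from 0.0025 to -0.033 with GSK-LSD1, so these splits are not read as results. Among the genes called for ATRA alone, 99.6% had the same sign with MB3 and 99.4% with GSK-LSD1. Across those genes, which are not independent replicates, the log2 differences had a Pearson correlation of 0.972 with MB3 and 0.971 with GSK-LSD1, and over all 11833 tested genes of 0.887 and 0.891 (Spearman 0.806 and 0.809). The retinoid list had 14 of 19 members higher and 2 lower in each (camera adjusted p = 4.83e-12 and 3.86e-12; adjusted p = 0.0394 and 0.0355 with an estimated correlation).

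The differences between those responses were tested as interactions. For ATRA by MB3, ATRA by GSK-LSD1, and MB3 by GSK-LSD1 under ATRA, edgeR called 0 genes, with and without the replicate block, and DESeq2 called 0. At an unadjusted p under 0.05 edgeR had 86, 78 and 163 genes and DESeq2 61, 68 and 140, and camera called none of the 23 lists. The edgeR counts were 0.727%, 0.659% and 1.38% of the tested genes, under the share of 0.05 of a calibrated test without effects. The lack of calls therefore does not exclude interactions. The smallest p-values, none past the threshold, belonged to BAIAP2 for ATRA by MB3 (contrast 1.05, SE 0.235), GTF2H2B for ATRA by GSK-LSD1 (contrast 2.73, SE 0.845) and UBE2B for MB3 by GSK-LSD1 (contrast 0.48, SE 0.133), each with adjusted p = 1. For ITGAM the interaction contrasts were 0.02 (SE 0.548), 0.43 (SE 0.548) and -0.44 (SE 0.464), and for CD38 -0.27 (SE 0.325), -0.02 (SE 0.331) and 0.02 (SE 0.291). The median SE of an interaction contrast with ATRA over the tested genes was 0.171 with MB3 and 0.172 with GSK-LSD1 on the log2 scale.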

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

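The fit without the pair of libraries that stood apart, and the replicate block with a correction for GC content and gene length, were chosen after seeing the data, as were the averaged effects of MB3 and GSK-LSD1. Of 364 called values of named genes, 258 kept their direction and call under every alternative run for them, 106 lost the call under at least 1 and 0 reversed. A left-out library ended 101 of these calls. Fewer libraries were then tested, and whether other causes acted was not tested.

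The replicate block called 3141 genes for ATRA against untreated, 23 for MB3, 13 for ATRA+MB3 against ATRA, 33 for both inhibitors with ATRA against ATRA, and 25 for that group against ATRA+GSK-LSD1. It called 3546 for both inhibitors with ATRA against untreated, 3204 for ATRA+MB3 against MB3, 2988 for ATRA+GSK-LSD1 against GSK-LSD1, 4112 for any difference, and 162 and 5 for the averaged MB3 and GSK-LSD1 effects. With the GC and length correction added, the counts in the same order were 4286, 47, 55, 73, 71, 4622, 4357, 4256 and, for the averaged effects, 398 and 10, and ATRA+GSK-LSD1 against ATRA had 3. The block takes out the spread that libraries of the same number share, and leaves 12 residual degrees of freedom against 14. For ATRA against untreated the median SE was 0.122 without the block and 0.094 with it. The correction also removes each library's mean deviation across genes, and the median log2 difference between groups with and without ATRA moved to negative values. Beyond this recentring, the cause of the further calls with the correction was not tested.

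DESeq2 called 0 genes for GSK-LSD1 against untreated, 5 for ATRA+MB3 against ATRA, 7 for both inhibitors with ATRA against ATRA and 7 against ATRA+GSK-LSD1, 1 against ATRA+MB3, and 56 and 4 for the averaged effects. A fit to only the groups of a contrast, which has fewer samples, called 8 for MB3, 0 for GSK-LSD1, 0 for ATRA+MB3 against ATRA, 0 for both inhibitors with ATRA against ATRA and 0 against ATRA+GSK-LSD1. It called 1251 against untreated, and 14 and 1 for the averaged effects. The filter of 1 CPM gave 3 for MB3 and 0 for GSK-LSD1, and no filter gave 1 for averaged GSK-LSD1. Without both libraries that stood apart the counts were 9 for MB3, 0 for GSK-LSD1, 8 for both inhibitors with ATRA against ATRA, 10 against ATRA+GSK-LSD1 and 49 for averaged MB3, and the cause was not tested.

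Leaving out each library in turn gave 1255 to 1844 genes for ATRA, 2 in each case for MB3, 0 for GSK-LSD1, 0 to 2 for ATRA+MB3 against ATRA, and 0 for ATRA+GSK-LSD1 against ATRA. It gave 0 to 5 for both inhibitors with ATRA against ATRA, 0 to 6 against ATRA+GSK-LSD1, 0 against ATRA+MB3 and 1573 to 2484 against untreated. The ranges were 1310 to 2007 for ATRA+MB3 against MB3, 1198 to 1751 for ATRA+GSK-LSD1 against GSK-LSD1, 0 for the interactions, 11 to 30 for averaged MB3 and 1 to 3 for averaged GSK-LSD1.

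Of 23 lists, camera with an estimated correlation called 1 for ATRA against untreated, 1 for MB3, 0 for GSK-LSD1, 1 for ATRA+MB3 against ATRA, 0 for ATRA+GSK-LSD1 against ATRA, 1 for both inhibitors with ATRA against ATRA, 1 against ATRA+GSK-LSD1, 0 against ATRA+MB3 and 2 against untreated. It called 1 for ATRA+MB3 against MB3, 1 for ATRA+GSK-LSD1 against GSK-LSD1, and 1 and 0 for the averaged effects. The rotation test fry, which does not compare a list with other genes, called 1 for MB3, 0 for GSK-LSD1, 1 for ATRA+MB3 against ATRA, 0 for ATRA+GSK-LSD1 against ATRA, 1 for both inhibitors with ATRA against ATRA, 1 against ATRA+GSK-LSD1, 0 against ATRA+MB3, and 1 and 0 for the averaged effects. The block in the voom design gave 2 lists for ATRA+GSK-LSD1 against ATRA. With the block and an estimated correlation together the counts were 5 for ATRA against untreated, 3 for MB3, 1 for GSK-LSD1, 5 for ATRA+MB3 against ATRA and 2 for ATRA+GSK-LSD1 against ATRA. They were 9 for both inhibitors with ATRA against ATRA, 7 against ATRA+GSK-LSD1, 0 against ATRA+MB3 and 7 against untreated, 5 for ATRA+MB3 against MB3, 4 for ATRA+GSK-LSD1 against GSK-LSD1, and 8 and 2 for the averaged effects. At these depths the simulated 1.5-fold changes were recovered in 70.15% of cases. That share can be too high for the real comparisons, since the simulation lacked the spread of replicate numbers and the libraries that stood apart. The low counts for the inhibitors therefore do not exclude changes of this size.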

Other observations

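The averaged effects of MB3 and GSK-LSD1 were chosen after seeing the data. Also chosen after the result was seen were the tests for mislabelled libraries, the draws that keep the replicate numbers together, the test of GC content and gene length on the libraries that stood apart, and the replicate block with the GC and length correction.

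MB3 was averaged over its 3 backgrounds, which share no library. EdgeR called 29 genes, 26 higher and 3 lower, with 162 with the replicate block (112 higher and 50 lower), 398 with the block and the GC and length correction (259 higher and 139 lower) and 56 by DESeq2 (44 higher and 12 lower). Of the 23 NRF2 genes 9 rose, 14 with the block and 16 adjusted over the list alone (camera adjusted p = 2.21e-33; adjusted p = 2.47e-05 with an estimated correlation). OSGIN1 rose by 2.01 (SE 0.153, adjusted p = 2.06e-07), GCLM by 0.65 (SE 0.0878, adjusted p = 0.000622) and NQO1 by 0.53 (SE 0.0758, adjusted p = 0.00108), each higher in 9 of 9 pairs of libraries with the same number. S1PR3, a sphingosine phosphate receptor, rose by 0.55 (SE 0.0699, adjusted p = 0.000272). Of the 3 genes that fell, MIR155HG, the host gene of the microRNA miR-155, fell by 0.53 (SE 0.0949, adjusted p = 0.0156, lower in 8 of 9 pairs), a call lost without Untreated replicate 1 or MB3 replicate 2 (adjusted p over the alternatives 7.87e-05 to 0.0629). Its log2 difference was -0.67 in untreated cells and -0.79 with ATRA, but only -0.135 with ATRA and GSK-LSD1. The other 2, ARRDC3 and ALAS1, lost the call under 19 and 11 of 26 alternatives, with adjusted p up to 0.125 and 0.0878 and lows of 0.000115 and 2.13e-05. The count fell to 11 without MB3 replicate 2, 12 without Untreated replicate 1, 13 without ATRA replicate 3, 14 without ATRA replicate 1 or ATRA+GSK-LSD1+MB3 replicate 2 and 15 without Untreated replicate 3. It was 16 without ATRA+GSK-LSD1 replicate 1, ATRA+MB3 replicate 2, ATRA+GSK-LSD1 replicate 3 or MB3 replicate 3, and 19 without Untreated replicate 2. The calls of OSGIN1, GCLM, NQO1 and S1PR3 were kept in every alternative run.

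With averaged MB3 camera called 10 lists besides NRF2 with the preset correlation, in which few members or none were called without the block. All 18 heat shock genes had a positive difference, with 0 called and 5 adjusted over the list alone (camera adjusted p = 2.30e-11; adjusted p = 0.077 with an estimated correlation), and 5 called with the replicate block. All 21 cholesterol genes had a negative difference, from -0.32 to -0.03, with 0 called by edgeR, also adjusted over the list alone, and 9 called lower with the block (camera adjusted p = 1.45e-05; adjusted p = 0.513 with an estimated correlation). The integrated stress list had 24 of 26 positive differences and 1 call, with 3 adjusted over the list alone and 3 with the block (camera adjusted p = 3.38e-08; adjusted p = 0.153 with an estimated correlation). The unfolded protein list had 18 of 19 positive differences and 0 calls, with 4 with the block (camera adjusted p = 7.29e-08; adjusted p = 0.153 with an estimated correlation). With the block and an estimated correlation together the adjusted p was 0.0147 for heat shock, 9.44e-05 for cholesterol, 0.0302 for integrated stress and 0.0074 for the unfolded protein list. Of the other 6 lists, immediate early (adjusted p = 1.66e-05), G2/M (adjusted p = 0.00177), cell death (adjusted p = 0.00187), glycolysis (adjusted p = 0.0362) and granulocyte genes (adjusted p = 0.0472) were higher and the HOX and stem cell list lower (adjusted p = 0.0398). Their adjusted p was 0.153, 0.513, 0.077, 0.268, 0.573 and 0.153 with an estimated correlation. In these 6, 1 immediate early and 1 cell death gene were called, and with the block 2 of each, 1 G2/M and 1 glycolysis gene higher, and 1 HOX or stem cell gene higher and 2 lower.

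GSK-LSD1 averaged over its 3 backgrounds called 2 genes by edgeR, both higher, with 158 at an unadjusted p under 0.05, 5 with the replicate block and 4 by DESeq2. GPR65, a proton-sensing receptor, rose by 0.59 (SE 0.0762, adjusted p = 0.00211) and GFI1, a repressor that recruits LSD1, by 0.20 (SE 0.0334, adjusted p = 0.0408), each higher in 9 of 9 pairs of libraries with the same number. Both belong to the fixed list of LSD1 inhibitor response genes, which was higher (camera adjusted p = 1.91e-06; adjusted p = 0.0998 with an estimated correlation). The list of monocyte genes was higher too, with 0 of 19 called (camera adjusted p = 0.0425; adjusted p = 0.975 with an estimated correlation). Camera with the block and an estimated correlation together called 2 of 23 lists, against 0 with an estimated correlation alone. The count was 1 without any library of replicate 3 in these groups, without replicate 1 of ATRA+GSK-LSD1, ATRA, GSK-LSD1 or Untreated, and without replicate 2 of ATRA+MB3, ATRA+GSK-LSD1+MB3 or Untreated. The GFI1 call was lost without any of these 13 libraries or ATRA replicate 2, without a low-count filter and in a fit to these groups alone, with adjusted p from 4.18e-06 to 0.17. The GPR65 call was kept in every alternative run, with adjusted p from 1.85e-06 to 0.0101.

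The first pattern is the rise of the NRF2 list with MB3 in all 3 backgrounds. With every library thinned to the lowest total, the list's mean log2 difference kept at least 96.7% of its size in the 3 comparisons. Thinning leaves the expected share of each gene in a library unchanged, so little fall was possible and this decides nothing about library size. After removal of each library's trend over GC content and length the list's mean log2 difference kept at least 94.9%, which argues against that bias as the whole cause. In 9 of 9 libraries titled with MB3 the list mean lay above that of all libraries without MB3 of the same ATRA status, which restates the rise and so decides nothing about a mislabelled sample. That explanation stays open, as does an effect of the solvent in place of MB3, because no vehicle is named in the labels.

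The second pattern is that ATRA+MB3 replicate 1 and ATRA+GSK-LSD1+MB3 replicate 1 deviated from their group means together, with a correlation of 0.67 across genes. It was still 0.61 after removal of each library's trend over GC content and length, which argues against that trend as the whole cause. The trend explained 15.9% and 30.6% of their variance, and 30.3% in ATRA+GSK-LSD1+MB3 replicate 3, which is not of the pair. Deviations from a group mean cancel within the group, so the value of replicate 3 partly mirrors that of replicate 1. It does not decide whether the trend is particular to the pair. All 4 list means lay above every library without ATRA (retinoid list) or without MB3 under ATRA (NRF2 list). The retinoid means, 4.921 and 4.947 against at most 3.4 without ATRA, argue against samples without ATRA under these titles. The NRF2 means were 5.852 and 5.886, against 5.869 to 5.942 in the other libraries with ATRA and MB3 and at most 5.657 with ATRA without MB3. The rise with MB3 is also seen in libraries outside the pair, so these means argue against samples without MB3 under these titles. A swap of the pair with each other stays open. That test was chosen with the outcome of an earlier version known, in which 2 of 4 list means lay within the widened range of the libraries of the same ATRA and MB3 status, and it replaced it because a library that deviates for any reason can fail that version. The low retinoid mean is not particular to the pair, since ATRA replicate 1 was at 4.915 and ATRA+GSK-LSD1 replicate 1 at 4.93. Replicates 2 and 3 with ATRA lay between 5.119 and 5.272. A shared step of handling, or a difference of these cultures in their response to ATRA with MB3, stays open, and neither was tested.

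The third pattern is the rise of GPR65 and GFI1 with averaged GSK-LSD1. The median ratio of their log2 differences after to before the GC and length correction was 1, which argues against that bias. After to before thinning of all libraries to the lowest total the ratio was 1.02. Thinning keeps the expected share of each gene, so that ratio decides nothing about library size. What else led to the rise was not tested.

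Other groupings of the libraries were counted for each comparison. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In the 9 comparisons with calls the real split called 1844, 5, 1, 3, 3, 3, 2170, 1837 and 1737 genes (ATRA, MB3 and GSK-LSD1 against untreated; ATRA+MB3 against ATRA; both inhibitors with ATRA against ATRA, ATRA+GSK-LSD1 and untreated; ATRA+MB3 against MB3; ATRA+GSK-LSD1 against GSK-LSD1). In each of these 1 of 10 splits gave as many genes, the real one, and the highest other was 0. For ATRA+GSK-LSD1 against ATRA the real split and the highest other called 0, so 10 of 10 gave as many. For both inhibitors with ATRA against ATRA+MB3 the real split called 0 and the highest other 1308. The 3 other splits with calls put the replicates 1 of the groups on the same side, which points to a structure of these libraries, and among the 4 splits that part all 3 number pairs the highest other was 0.

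For the interactions the real count was 0, so all 30 of 30 draws gave as many genes by construction and the draws decide nothing. The highest other was 0, 2 and 7.

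For any difference among the 7 groups 1 of 100 draws gave 2520 genes, the real one, with a highest other of 1. Averaged MB3 gave 29 in 1 of 100 draws, with a highest other of 0, and averaged GSK-LSD1 gave 2 or more in 4 of 100 draws, with a highest other of 1053. The 3 other draws as large for GSK-LSD1 all had the libraries that stood apart on the same side, and the highest of the 66 draws that parted them was 0. These draws broke up the replicate numbers, which can widen the residual spread and lower their counts. Labels were therefore also moved only between libraries of the same number, in 100 draws each. Without the block 1 of 100 gave as many genes, the real one, with a highest other of 483 for any difference, 0 for averaged MB3 and 0 for averaged GSK-LSD1. With the block the real counts were 4112, 162 and 5, again 1 of 100 each, with a highest other of 1211, 41 and 0. For the averaged effects the share of draws was under 0.05, but these effects were chosen after seeing the data. The draws do not allow for that choice, so chance is not excluded for them. For any difference chance can be excluded at a share under 0.05. That says only that the groups are not all alike, and the draws mix libraries with and without ATRA. For GSK-LSD1 the count of 2 stays small and depends on single libraries, as given above.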
